A study of Mus musculus with 10 samples.

How the data were processed

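RNA from the middle of the mouse small intestine (the jejunum) was measured on 10 Affymetrix whole-transcript arrays, 5 from mice with Pcyt1a targeted in the intestinal epithelium and 5 from floxed controls. Per the labels' protocols, RNA was extracted with Trizol and cleaned on RNeasy columns, and 400 ng was turned into biotin-labelled target with the WT Plus kit. Per the submitters' processing notes, the arrays were processed with Affymetrix Expression Console 1.4.1.46 and RMA, a method that corrects background, brings the arrays to a shared distribution and summarises the probes of each probe set. Other settings of that step are not given in the sources used here. The deposited values are intensities on a linear scale, written with 1 decimal, and they ran from 1.8 to 15278.7, with array medians between 45.8 and 48.1. The design had assumed log2 values. Since the values were linear, log2 was taken first and the planned test was kept. Because RMA had already made the arrays alike in distribution, a shift shared by most transcripts would not be visible in these values. Detection calls were not used here, so dim probe sets were tested with the rest, and the number of arrays limits the precision.

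Samples were assigned to knockout or control from their titles, which also give replicate numbers 1 to 5 in each group. No column of the value table was left unmapped. The labels do not state outright that each array holds a separate animal. The p-values measure the spread between these samples, which may be technical in part.

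Probe sets were named from GEO's platform annotation. Of 41345 probe sets, 23521 carried 1 gene symbol, 1814 carried several and 16010 were unnamed. Probe sets with several symbols or none were left out of the gene test. For the 1082 genes with several probe sets, the one with the highest mean over all 10 arrays was used, which left 22180 genes. Of these, 21994 were found by Entrez identifier in a RefSeq gene table (assembly GRCm38.p6), and 0 of their symbols differed. That table was used for names and gene order, and no coordinates are given.

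Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on log2 intensity, group as the only term, without a trend and without the robust option. P-values were adjusted by Benjamini-Hochberg over the 22180 genes, and genes with adjusted p under 0.05 were called. For Pcyt1a, a two-sided exact permutation test over all 252 assignments of the arrays was run too. The test was checked on simulated data with the means and spreads of these genes, in the comparison of knockout against control. It recovered 36% of 50 genes changed by 0.5 on the log2 scale, 91% of 100 changed by 1 and 98% of 50 changed by 2, with 9 false calls among 167. The simulated noise was independent between genes, without variation shared within an array, so these rates may not hold for the real arrays.

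A total of 39 gene lists were fixed before the data were examined. They cover lipid metabolism, stress responses, epithelial cell types, position along the gut, immune and stromal cells and possible contaminating tissue, and 608 of their 678 genes were measured. The 38 lists with at least 5 measured members were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg over the lists. Camera compares a list with the other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way, were alternatives. In a simulation of knockout against control with 22180 genes, independent between genes, a list shifted by 0.5 was called and 1 of 38 lists was called in all. A list mean is the mean over its measured members of each log2 value minus that gene's mean over the 10 arrays, and its SE comes from the arrays.

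The genes to be named were set by a rule written before the data were examined. The rule takes Pcyt1a, the 15 largest increases and the 15 largest decreases among called genes whose knockout arrays all lay on 1 side of all control arrays, and up to 4 members of each list with the smallest p, given whether or not they passed. Numbered gene models, small RNAs and receptor segments were counted and not named. Any gene outside the rule is said to be so where it appears.

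Alternatives planned beforehand were a shift of each array to a shared median, quantile normalization of the tested genes, omission of the dimmest 30% of genes, the mean of a gene's probe sets, eBayes with trend and robust fitting, array weights, the replicate number as a block, omission of each array in turn, a minimum change of 1.5-fold, a threshold of 0.1, and a test of all probe sets. After the data were seen, 3 more were added: the mean of the ileum list as a covariate, the mean of the Paneth, stem cell and proliferation lists as a covariate, and omission of knockout 1 and control 5 together.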

Results

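Mice carried a floxed Pcyt1a gene, which encodes CTP:phosphocholine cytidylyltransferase alpha, the enzyme of the rate-limiting step in phosphatidylcholine (PC) synthesis. The knockout group also carried a tamoxifen-inducible Cre recombinase driven by the villin promoter, which is active in the intestinal epithelium. Both groups received tamoxifen for 5 days. They were females of 10 to 12 weeks, which ate high-fat food during 3 days, fasted overnight and then had 2 hours of the same food before a piece of 3 cm was taken from the jejunum. The comparison of 5 knockout with 5 control arrays asks how the transcripts of the fat-fed jejunum differ when Pcyt1a is targeted in its epithelium. Only the knockout group carried Cre, so an effect of active Cre itself cannot be told apart from loss of Pcyt1a. PC itself was not measured here. Median intensity per array over all probe sets lay between 45.8 and 48.1, and Pearson correlations between arrays across the tested genes were 0.972 to 0.993.

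Pcyt1a was lower in every knockout array. Its log2 intensity was 7.51 ± 0.16 (SD, n = 5) in knockout and 9.22 ± 0.20 (SD, n = 5) in control, a difference of -1.71 (SE 0.11, 95% confidence interval -1.96 to -1.46, limma adjusted p = 6.51e-05). This is 3.27-fold lower (2.75 to 3.89), or 30.6% of the control level. Knockout arrays ranged from 7.24 to 7.66 and control arrays from 8.95 to 9.51, and the two-sided exact permutation p was 0.00794, the smallest that 252 assignments can give. The tissue also holds cells in which villin is not active, and the sources used here do not say which probes lie in the deleted part of the gene.

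**Figure D1:**
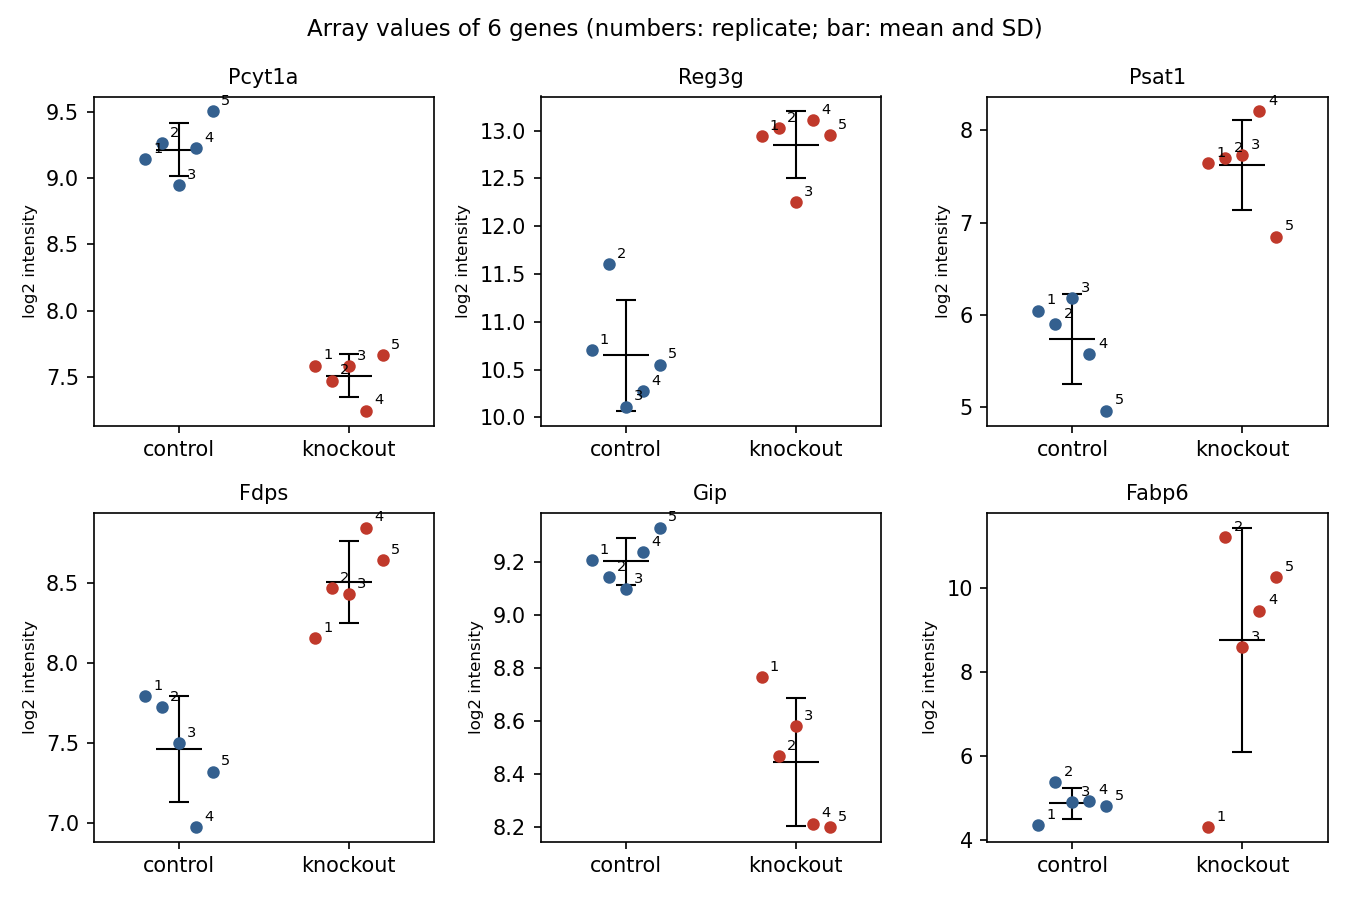
Log2 intensity of 6 genes on each array, controls in blue and knockouts in red, with replicate numbers beside the points and bars for the mean and SD of 5 arrays. Pcyt1a, Reg3g, Psat1, Fdps and Gip separate the groups fully, while Fabp6 was 4.31 in knockout 1 and 8.59 to 11.20 in the other knockouts.

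Of 22180 genes, 76 were called, 38 higher and 38 lower in knockout, and 30 of them differed at least 2-fold (14 higher, 16 lower). Among called genes, the highest increases were in Reg3g, a bactericidal lectin of the epithelium (4.61-fold), Oas1g, of the interferon-induced oligoadenylate synthetase family (4.57-fold), Psat1, an enzyme of serine synthesis (3.72-fold), and Clca3a1 (3.71-fold). The deepest decreases among them were in Cyp2c66, a cytochrome P450 (4.67-fold lower), S100g, the calcium-binding protein calbindin-D9k (3.45-fold lower), and the pseudogene Tmem229b-ps (3.31-fold lower). In all 76 called genes the knockout arrays lay on 1 side of all control arrays. Over all genes this held for 614 (2.77%), and chance gives 0.794%. At an unadjusted p under 0.05 there were 2678 genes, where 1109 would be expected by chance. The count depended on the arrays used. It was 268 without knockout 1, 11 without knockout 2, 29 without knockout 3, 12 without knockout 4 and 59 without knockout 5. It was 18, 16, 50, 15 and 36 without controls 1, 2, 3, 4 and 5. With the ileum list mean of each array as a covariate, chosen after seeing the data, 5 genes were called, 4 of them among the 76.

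**Figure D2:**
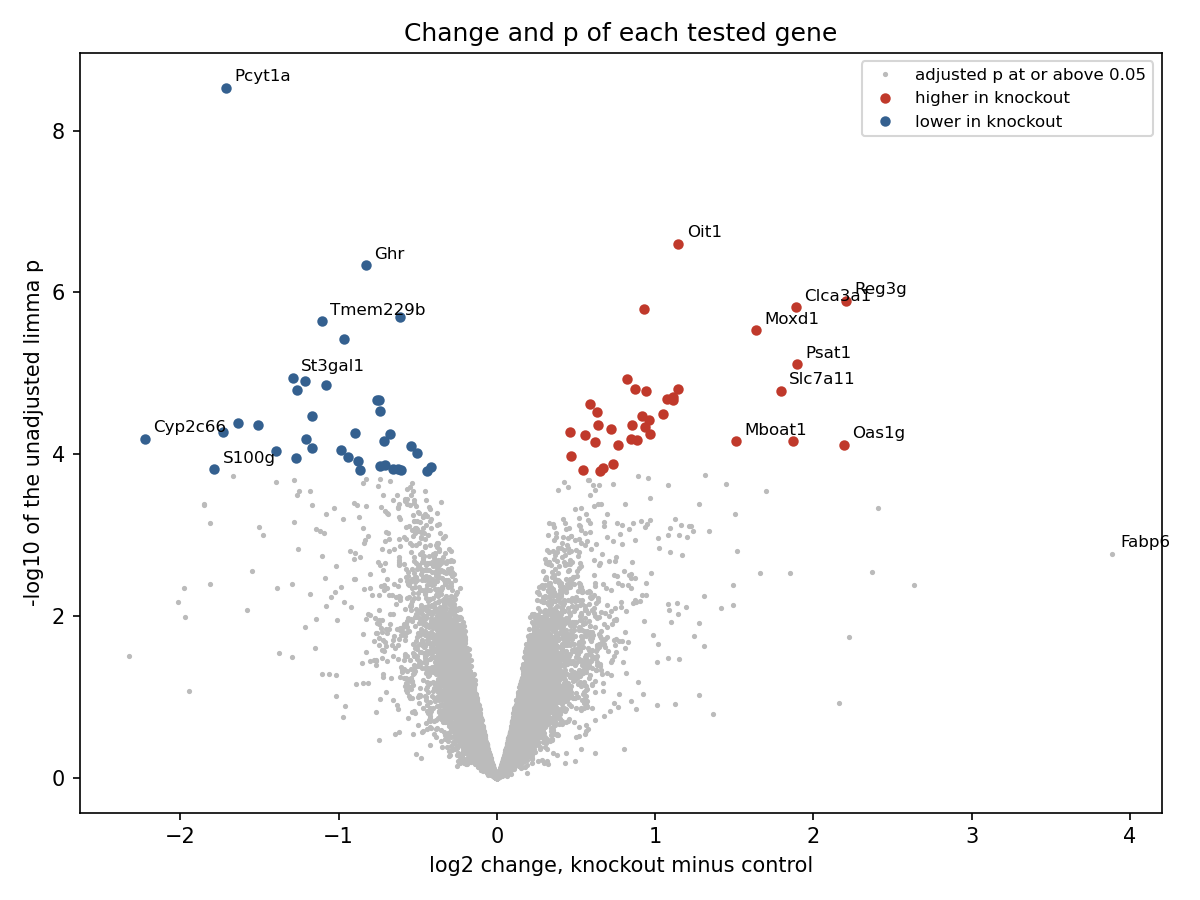
Each point is 1 of 22180 genes, with the log2 change (knockout minus control) on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 38 genes called higher are red and the 38 called lower are blue; Fabp6 has the rightmost value, 3.89, and did not pass.

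Among the other large increases were Ptk6 (1.87 on the log2 scale, SE 0.32), an epithelial tyrosine kinase, Moxd1 (1.64, SE 0.20), Oit1 (1.15, SE 0.11), Gsr (1.14, SE 0.17), which encodes glutathione reductase, and Gmds (1.12, SE 0.17), an enzyme of GDP-fucose synthesis. Ripk3 (1.11, SE 0.17), a kinase of necroptosis, Akr1b8 (1.07, SE 0.16), an aldo-keto reductase, and Prss32 (0.97, SE 0.16) also rose. Decreases included Rdh16f2 (-1.64, SE 0.26), of the retinol dehydrogenase family, Dipk2a (-1.51, SE 0.24), Dao (-1.40, SE 0.25), the peroxisomal D-amino acid oxidase, St3gal1 (-1.29, SE 0.18), a sialyltransferase, and Nrg4 (-1.27, SE 0.23), an ErbB ligand. Tmc7 (-1.26, SE 0.19), Ces1d (-1.21, SE 0.17), a carboxylesterase, Cym (-1.21, SE 0.20), Hsd3b3 (-1.17, SE 0.20), a steroid dehydrogenase, Sprr1a (-1.17, SE 0.18) and Tmem229b (-1.11, SE 0.13) fell too. Limma adjusted p in these 2 groups of genes ran from 0.00276 for Oit1 to 0.0395 for Nrg4. Reg3g, Oas1g, Clca3a1, Cyp2c66, Rdh16f2 and the pair Tmem229b and Tmem229b-ps have close relatives in the genome, and their probes may not tell these apart. The 36 called genes named by rule besides Pcyt1a all kept their direction under 20 alternatives. Since the groups did not overlap in these genes, leaving out or weighting arrays could not turn that direction. Moxd1 and Oit1 passed under all 20, while S100g and Nsdhl passed under 8, Dao, Nrg4, Per1, Ptk6, Siglecf and Sst under 9, Cyp2c66, Mboat1, Hsd3b3 and Tmem229b-ps under 10 and the other 22 under 11 to 19.

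In the list of PC and phosphatidylethanolamine (PE) synthesis, 1 of 18 measured genes fell, Pcyt1a itself, and the other 17 did not pass. Adjusted over the list alone, 4 fell and 1 rose. The next members by p had values of -0.55 (SE 0.13) for Pisd, which makes PE from phosphatidylserine, -0.70 (SE 0.20) for Chka, the choline kinase ahead of Pcyt1a in the pathway, and 0.62 (SE 0.18) for Slc44a4, a choline transporter-like protein. The pseudogenes Pisd-ps3 (0.85, SE 0.14) and Pisd-ps2 (0.73, SE 0.13), outside the naming rule and picked after the calls were seen, were called higher. Their probes and those of Pisd may not tell these apart. The list mean was -0.15 (SE 0.03), camera's adjusted p was 0.158 and fry's 0.0191, all with Pcyt1a included. Without Pcyt1a the mean of the other 17 was -0.06 (SE 0.03), and of all 18 members 9 had higher and 9 lower values, with a median of -0.00624. Among the phospholipid remodelling genes, Mboat1, a lysophospholipid acyltransferase, rose (1.51, SE 0.26, adjusted p = 0.0296) and 22 of 23 did not pass. Adjusted over the list alone, 2 rose and 1 fell, with Lpcat4 at 1.23 (SE 0.28), Agpat3 at -0.51 (SE 0.14) and Pla2g1b at -0.32 (SE 0.11). Its mean was 0.29 (SE 0.12), with a camera adjusted p of 0.0219. The call ended with an estimated correlation (adjusted p = 0.264) and with fry (adjusted p = 0.118). It also ended without knockout 5 (0.0702), without control 5 (0.0948) and with the ileum covariate, where the mean was 0.06 (SE 0.07).

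Cholesterol synthesis genes stood higher in knockout as a list. Fdps, which makes farnesyl diphosphate, and Nsdhl, a sterol dehydrogenase, rose by 1.05 (SE 0.16) and 0.67 (SE 0.12), 18 of 20 measured members had higher values, and 18 did not pass over all genes. Adjusted over the list alone, 12 rose and 0 fell. Sqle, squalene epoxidase, was at 1.21 (SE 0.27) and Mvk, mevalonate kinase, at 0.64 (SE 0.13). On average the list stood 0.45 higher (SE 0.11), and all 5 knockout arrays lay above all controls. The lowest knockout array, knockout 1, was at -0.038 and the highest control, control 1, at -0.061. Camera's adjusted p was 1.32e-11 and fry's 0.0191, and the adjusted p was 0.165 with an estimated correlation. With the ileum covariate the mean was 0.30 (SE 0.11). For fatty acid synthesis, 0 of 16 genes passed, and adjusted over the list alone 1 rose and 1 fell. The values were -0.93 (SE 0.23) for Srebf1, the lipogenic transcription factor, 0.47 for Acaca, 0.44 (SE 0.10) for Elovl1 and 0.32 for Mid1ip1. As a list they averaged 0.17 (SE 0.11, camera adjusted p = 0.0136; adjusted p = 0.388 with an estimated correlation). It did not pass with fry (adjusted p = 0.212), nor without knockout 1 (0.0511), knockout 4 (0.0880, mean 0.11) or control 4 (0.0737). Its mean was 0.29 (SE 0.13) with the ileum covariate.

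Genes of fat absorption and chylomicron assembly had lower values in 21 of 26 cases, and 0 passed over all genes. Adjusted over the list alone, 6 fell and 1 rose. The 4 members with the smallest p were Cd36, a fatty acid transporter (-1.85, SE 0.39, adjusted p = 0.0709), Dgat2, a triglyceride-forming acyltransferase (-0.98, SE 0.28), Slc27a2, a fatty acid transport protein (-0.97, SE 0.30), and Apoc3 (-0.70, SE 0.19). The list mean was -0.26 (SE 0.10, camera adjusted p = 0.00321). The adjusted p was 0.573 with an estimated correlation and 0.285 with fry. With the ileum covariate the mean was -0.10 (SE 0.10), and the call ended there too. Knockout 1, the array with the lowest ileum list mean, was at 0.17, against -0.34 to -0.10 in the other knockouts and 0.00457 to 0.32 in controls. PPARA targets and fatty acid oxidation had a mean of -0.17 (SE 0.10, camera adjusted p = 0.0300; 0.573 with an estimated correlation), and 0 of 22 passed, with 2 higher and 4 lower adjusted over the list alone. Knockout 1 was at 0.14, the other knockouts at -0.21 to -0.09 and the controls at -0.12 to 0.32. Members went both ways, with Slc25a20 at -0.40 (SE 0.11), Hadhb at -0.32 (SE 0.08), Acadl at 0.52 (SE 0.13) and Cyp4f14 at 0.38 (SE 0.09). With the ileum covariate the mean was 0.00641 (SE 0.07). Its call also ended with fry (adjusted p = 0.341), quantile normalization (0.0520) and array weights (0.0555). Without knockouts 2, 3 or 5 or controls 3 or 5 it ended too (adjusted p of 0.0810, 0.0512, 0.0821, 0.120 and 0.122). Sterol transport was not called (-0.10, SE 0.11, adjusted p = 0.351; 0 of 11 past the test, Nceh1 at -0.62), except, at -0.28, with the ileum covariate (0.00292), and with 1 array left out its mean ran from -0.17 to -0.04.

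Targets of ATF4, the transcription factor of the integrated stress response, stood higher in knockout. Psat1 (1.89, SE 0.26), the cystine transporter gene Slc7a11 (1.79, SE 0.26) and the glutathione-degrading Chac1 (0.96, SE 0.15) rose, and 19 of 22 members did not pass. Asns, asparagine synthetase, was at 1.31 (SE 0.25, adjusted p = 0.0521). Adjusted over the list alone, 8 rose and 0 fell. The list mean was 0.48 (SE 0.11), with a camera adjusted p of 3.51e-06 and a fry adjusted p of 0.0191. The adjusted p was 0.165 with an estimated correlation. Every knockout array lay above every control, though knockout 5, at -0.063, was close to control 3, at -0.086. With the ileum covariate the list mean was 0.50 (SE 0.15). A second probe set of Slc7a11 showed 0.12. Targets of ATF6 and XBP1, transcription factors of the endoplasmic reticulum stress response, were not called (mean -0.03, SE 0.08, camera adjusted p = 0.524), with 0 of 23 past the test and Herpud1 at -0.51. In the NRF2 list of oxidative stress genes, Slc7a11 rose and 14 of 15 did not pass, with Gclc at -0.48, Gstm1 at -0.45 and Gclm at -0.32. In this list 1 gene rose and 1 fell when adjusted over the list alone. Its mean of 0.07 (SE 0.07) and its median of -0.01 differ in sign, as do the directions of camera (down, adjusted p = 0.886) and fry (up, 0.965). In the apoptosis and p53 list, Ripk3 rose and 13 of 14 did not pass, with Bcl2l11 at -0.37, Mdm2 at -0.56 and Trp53inp1 at -0.49 (mean -0.02, SE 0.05, camera adjusted p = 0.515). Here 2 rose and 3 fell when adjusted over the list alone.

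**Figure D3:**
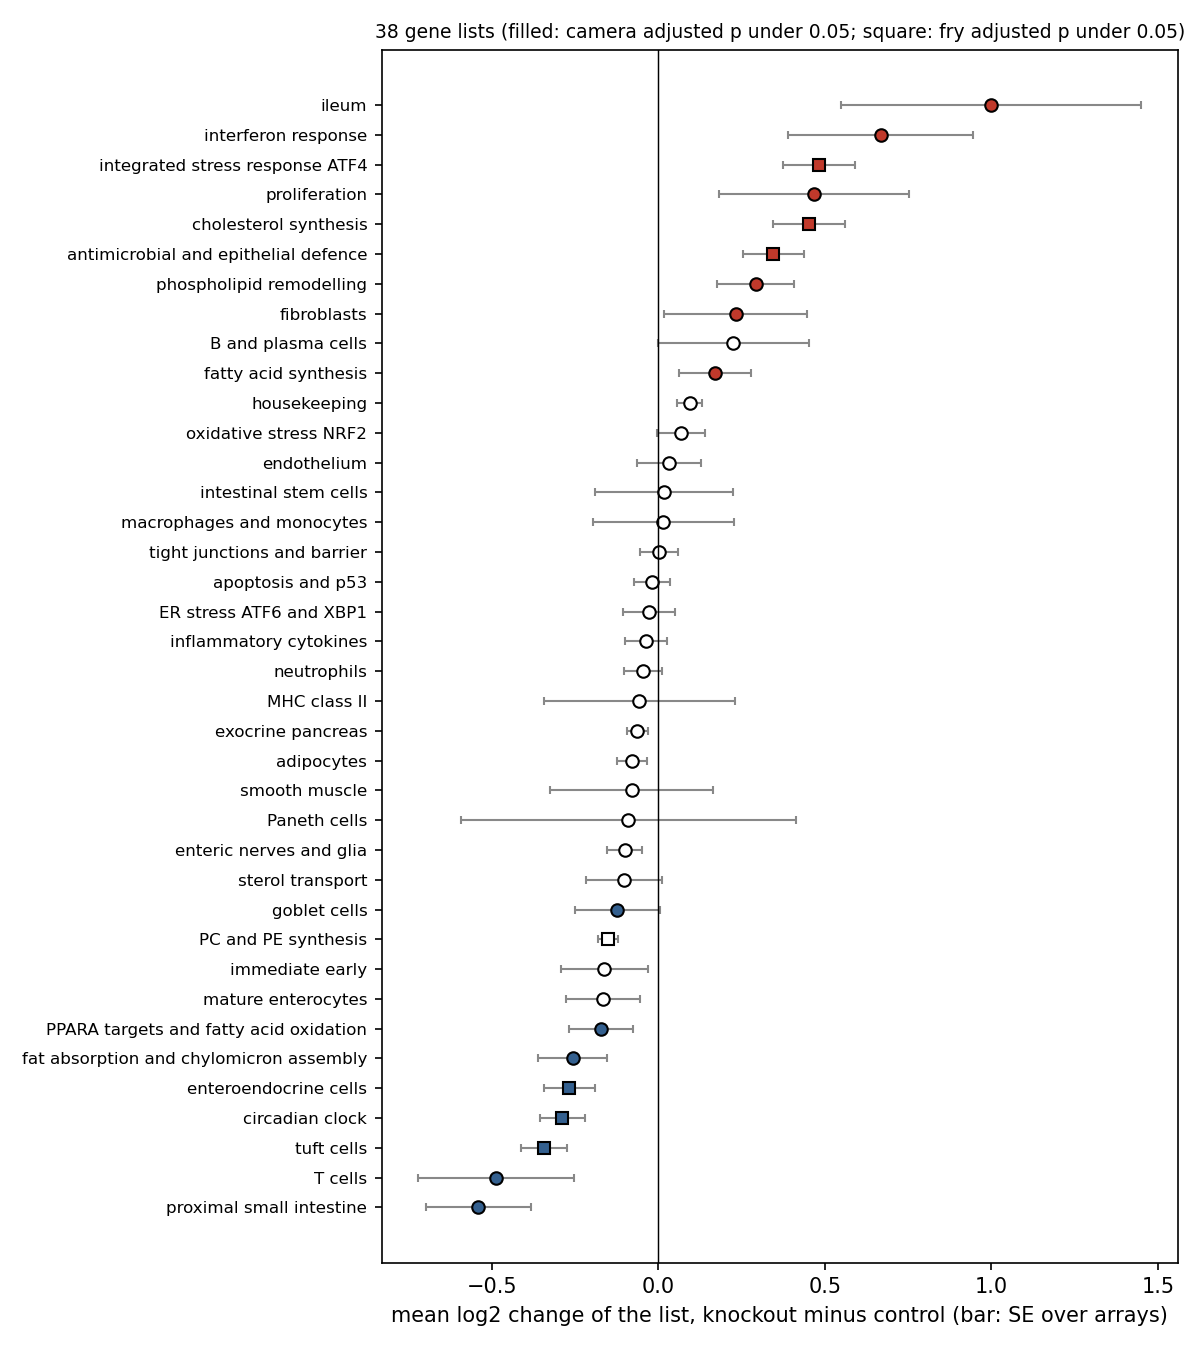
Mean log2 change of 38 gene lists, knockout minus control, with the SE over the 10 arrays. Filled points are the 17 lists with a camera adjusted p under 0.05 and squares the 7 with a fry adjusted p under 0.05; the means run from -0.54 for proximal intestine to 1.00 for ileum.

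Epithelial defence genes changed in both directions. Reg3g rose (2.20, SE 0.25) and Sprr1a fell (-1.17, SE 0.18), while 17 of 19 did not pass, and adjusted over the list alone 9 rose and 3 fell. The related lectins Reg3b and Reg3a stood at 0.97 (SE 0.20) and -0.88 (SE 0.18). The list mean was 0.35 (SE 0.09, camera adjusted p = 0.00698, fry 0.0297; adjusted p = 0.187 with an estimated correlation). The call ended without knockout 1 and control 5 together (0.0501). Interferon response genes had higher values in 19 of 21 cases, and 0 passed over all genes, against 6 that rose adjusted over the list alone. Mx2 was at 1.49 (SE 0.42), Oasl2 at 1.45 (SE 0.28, adjusted p = 0.0561), Isg15 at 1.34 (SE 0.31) and Irf7 at 0.92 (SE 0.27). Their mean was 0.67 (SE 0.28, camera adjusted p = 8.08e-08; adjusted p = 0.309 with an estimated correlation), and it differed widely among knockouts, from -0.17 in knockout 3 to 1.22 in knockout 5. Inflammatory cytokines (-0.04, SE 0.06, adjusted p = 0.708; Il6 at 0.30) and MHC class II genes (-0.06, SE 0.29, adjusted p = 0.829; H2-Oa at 0.22) were not called, with 0 of 22 and 0 of 8 genes past the test. The MHC class II list was called, at -0.28, without control 5 (0.0326).

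Markers of hormone-producing and tuft cells stood lower in knockout. Gip, an incretin hormone gene, and Sst, somatostatin, fell by 0.76 (SE 0.11) and 0.71 (SE 0.12) on the log2 scale, and 19 of 23 enteroendocrine genes had lower values, with 21 not past the test. Chga and Pcsk1 stood at -0.39 (SE 0.10) and -0.29 (SE 0.08). Adjusted over the list alone, 8 fell and 0 rose. The mean was -0.27 (SE 0.08, camera adjusted p = 3.51e-06, fry 0.0191; adjusted p = 0.165 with an estimated correlation). With the ileum covariate it was -0.31 (SE 0.10). In the tuft cell list, Siglecf fell (-0.50, SE 0.09), 12 of 13 had lower values and 12 did not pass, and adjusted over the list alone 11 fell. Siglecf is also a marker of eosinophils. Rgs13, Dclk1 and the taste channel gene Trpm5 had values of -0.62 (SE 0.13), -0.33 (SE 0.09) and -0.30 (SE 0.07). The mean was -0.34 (SE 0.07), with all knockout arrays below all controls (camera adjusted p = 1.17e-08, fry 0.0191; adjusted p = 0.165 with an estimated correlation), and -0.27 (SE 0.08) with the ileum covariate. For goblet cells the mean was -0.12 (SE 0.13, camera adjusted p = 0.00256; adjusted p = 0.459 with an estimated correlation) and 0 of 13 passed, with 4 lower adjusted over the list alone: Sytl2 (-0.61), Fcgbp (-0.45), Atoh1 (-0.39) and Tff3 (-0.38). That mean was -0.06 without knockout 5, -0.08 without control 1, -0.21 without control 5, -0.20 with the mean of the crypt lists as a covariate and -0.21 (SE 0.16) with the ileum covariate.

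Crypt and villus lists varied widely between arrays of the same group. Proliferation genes had higher values in 22 of 25 cases and 0 passed over all genes, with Birc5 at 0.86 (SE 0.19), Plk1 at 0.88, Cdc20 at 0.68 and Aurka at 0.64, and adjusted over the list alone 1 rose. The mean was 0.47 (SE 0.29, camera adjusted p = 2.25e-07; adjusted p = 0.468 with an estimated correlation), and array means ran from -0.48 to 0.68 in knockout and from -0.78 to 0.47 in control. It was 0.30 without knockout 1 and control 5 together. Paneth cells (-0.09, SE 0.50, adjusted p = 0.688; Clps at -0.89) and stem cells (0.02, SE 0.21, adjusted p = 0.708; Axin2 at 0.55) were not called, with 0 of 9 and 0 of 17 past the test. Control 5 had the lowest Paneth mean, -1.61, and without it the list was called, at -0.50 (0.00157), and at -0.37 without knockout 1 too (0.0220); without control 3 the stem cell list was called, at 0.14 (0.0459). Mature enterocyte genes were not called (-0.17, SE 0.11, adjusted p = 0.174), and 0 of 23 passed, with Lct, lactase, at -0.72 (SE 0.15, adjusted p = 0.0640) and 2 lower adjusted over the list alone. They were called at -0.22 without knockout 5 (0.0480) and without control 3 (0.0409), and at -0.28 with the ileum covariate (0.00465), while without knockout 4 the mean was -0.09. Tight junction genes were not called (mean 0.00220, SE 0.06, adjusted p = 0.367; 0 of 18 past the test), Cldn4 stood at -1.67 (SE 0.32, adjusted p = 0.0521), and the sign of the list mean turned under quantile normalization (-2.52e-04).

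Most listed genes of the distal intestine had higher values (10 of 11 ileum genes) and most of the proximal intestine lower ones (8 of 11). Fabp6, the ileal bile acid-binding protein, was at 3.89 (SE 0.97, adjusted p = 0.120), Slc10a2, the ileal bile acid transporter, at 2.23 (SE 0.82), Fgf15 at 1.16 (SE 0.26) and Slc51a at 0.67 (SE 0.17). In the ileum list 0 of 11 genes passed over all genes, and adjusted over the list alone 3 rose. Its mean was 1.00 (SE 0.45, camera adjusted p = 7.13e-04; adjusted p = 0.309 with an estimated correlation). It was -1.10 in knockout 1, 0.72 to 1.10 in the other knockouts and -0.89 to 0.18 in controls. In the proximal list S100g fell (-1.79, SE 0.33), 10 of 11 did not pass, and adjusted over the list alone 4 fell. Cyp2b10 was at -1.17 (SE 0.24) and Adh6a at -0.59 (SE 0.20). The mean was -0.54 (SE 0.16, camera adjusted p = 3.32e-04). The adjusted p was 0.264 with an estimated correlation and 0.0511 with fry. With the ileum covariate the mean was -0.24 (SE 0.11), and the call ended there too. Knockout 1 was at 0.21, within the controls (0.07 to 0.52), and the other knockouts were at -0.51 to -0.19.

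**Figure D4:**
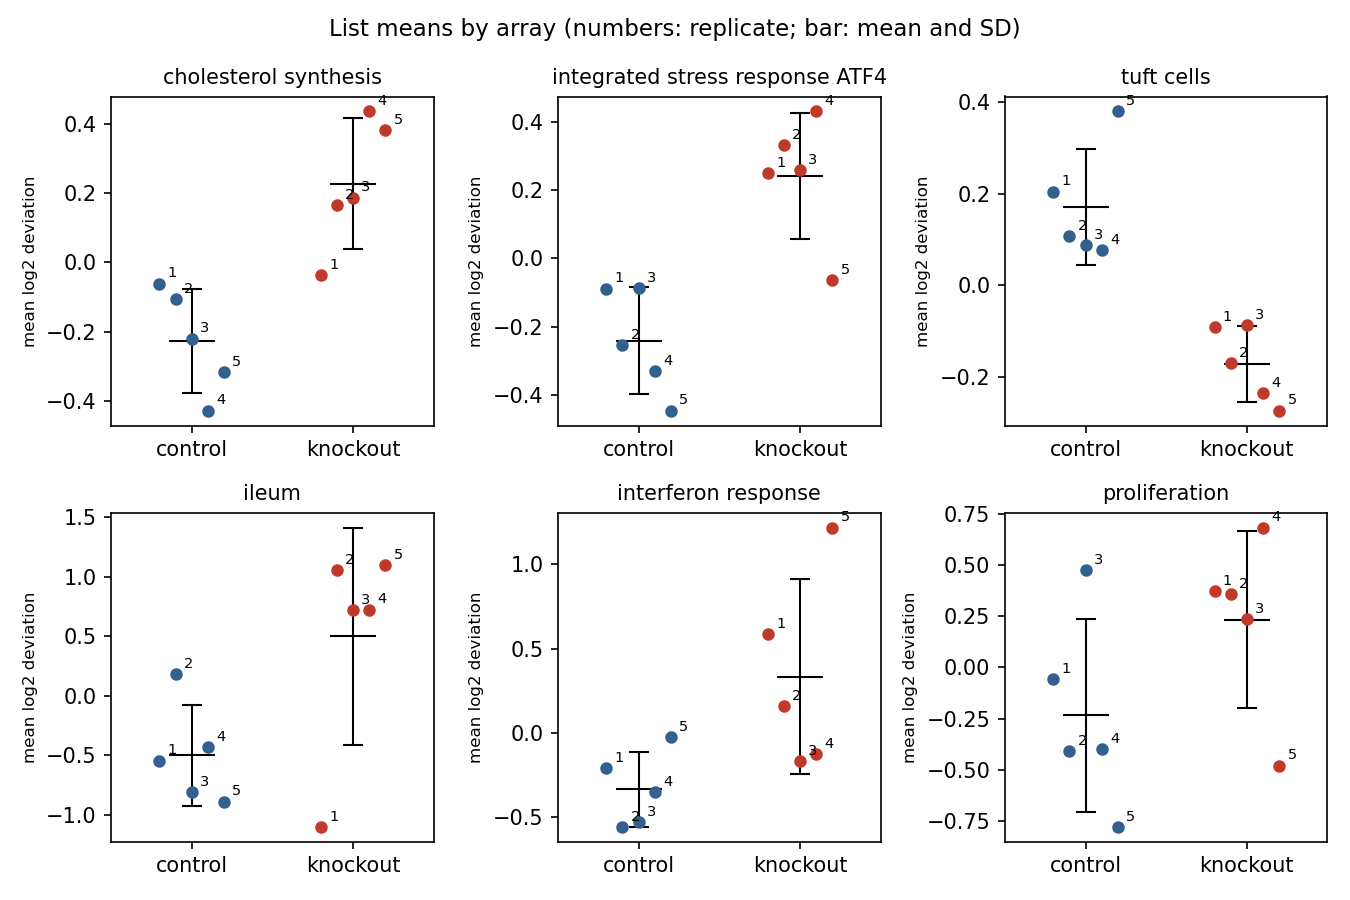
Mean log2 deviation of 6 gene lists on each array, controls in blue and knockouts in red, with replicate numbers beside the points and bars for the mean and SD of 5 arrays. The cholesterol, ATF4 and tuft cell lists separate the groups, while knockout 1 has the lowest ileum value, -1.10, and knockout 5 lies among the controls for proliferation, at -0.48.

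Clock genes stood lower as a list. Hlf and Per1 fell (-0.74, SE 0.11, and -0.68, SE 0.11), 13 of 15 did not pass, and adjusted over the list alone 6 fell and 1 rose. Bhlhe40 was at -1.09 (SE 0.25) and Ciart at -0.47 (SE 0.11), while Arntl, outside the naming rule and picked after its value was seen, was the 1 member higher in that count, at 0.59 (SE 0.15). The mean was -0.29 (SE 0.07, camera adjusted p = 3.34e-04, fry 0.0205; adjusted p = 0.187 with an estimated correlation). Immediate early genes were not called (-0.16, SE 0.13, adjusted p = 0.150; Fosb at -0.77) except, at -0.22, without knockout 2 (0.0265) and without knockout 1 and control 5 together (0.0499), while without knockout 4 or control 1 it was -0.10. Housekeeping genes were not called (0.09, SE 0.04, adjusted p = 0.142; Gusb at 0.40), except, at 0.13, with the ileum covariate (0.0476).

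Among other cell types, T cell genes had lower values in 15 of 16 cases and 0 passed, with Cd8a at -0.79, Cd3e at -0.76, Cd3g at -0.74 and Klrd1 at -0.69. The list mean was -0.49 (SE 0.23, camera adjusted p = 2.13e-05, or 0.309 with an estimated correlation) and -0.28 (SE 0.29) with the ileum covariate. Knockout 1 was at 0.26, within the controls (-0.15 to 0.80), and the other knockouts were at -0.77 to -0.11. Fibroblast genes had a mean of 0.23 (SE 0.22, camera adjusted p = 0.0136; adjusted p = 0.584 with an estimated correlation), with 0 of 14 past the test, Col3a1 at 0.58, Col1a1 at 0.55, Col1a2 at 0.42 and Sparc at 0.36. Fry did not call this list (adjusted p = 0.517). The camera call ended without knockout 5 (0.110, mean 0.15) and without control 5 (0.271, mean 0.07). It also ended with array weights (0.103, mean 0.14) and with the ileum covariate (mean 0.15, SE 0.29). Without knockout 1 and control 5 together it ended too (0.461, mean 0.04). B and plasma cells were not called (0.23, SE 0.23, adjusted p = 0.0697; Ms4a1 at 0.85), although they were without knockout 2 (0.0326), knockout 3 (0.0348) or control 2 (1.95e-05; mean 0.41), while without knockout 5 or control 5 the mean was 0.12. Macrophages (0.02, SE 0.21, adjusted p = 0.829; Itgam at 0.33), neutrophils (-0.04, SE 0.06, adjusted p = 0.556; Ly6g at -0.22) and smooth muscle (-0.08, SE 0.25, adjusted p = 0.546; Lmod1 at -0.22) were not called. Without control 5 macrophages were called at -0.17 (0.0160), and at -0.23 without knockout 1 too (0.00117), while smooth muscle was called at 0.15 without control 4 (0.0387). Nor were enteric nerves and glia (-0.10, SE 0.05, adjusted p = 0.150; Vip at -0.37), adipocytes (-0.08, SE 0.04, adjusted p = 0.208; Adipoq at -0.31) or exocrine pancreas (-0.06, SE 0.03, adjusted p = 0.546; Pnliprp1 at -0.63). The endothelial list was not called (adjusted p = 0.841, camera direction up; Lyve1 at 0.53), and its mean of 0.03 (SE 0.10) and median of -0.04 differ in sign. In these 7 lists and in the B and plasma cell list 0 genes passed over all genes. The 2 measured red blood cell genes were too few for a list test, with Slc4a1 at -0.22.

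In all, 17 of 38 lists were called by camera at the preset correlation. With an estimated correlation 0 of 38 were called, and the smallest adjusted p there was 0.165. A two-sided exact permutation test of each list mean over the arrays was run outside the plan. Its smallest adjusted p was 0.0754, for cholesterol synthesis, ATF4 targets, tuft cells and circadian clock. Its unadjusted p was 0.143 for proliferation, 0.167 for fatty acid synthesis, 0.333 for goblet cells and 0.349 for fibroblasts, all called by camera. Fry called 7, of which cholesterol synthesis, ATF4 targets, enteroendocrine cells, tuft cells, epithelial defence and circadian clock were also called by camera. The other lists called by camera did not pass fry, with adjusted p from 0.0511 for proximal intestine to 0.517 for fibroblasts. For the interferon, ileum, T cell, goblet cell and proliferation lists fry's adjusted p was 0.165, 0.197, 0.201, 0.206 and 0.310.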

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

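The tests of whether knockout 1 was mislabelled and of whether ileal genes were higher in every knockout array, and the tests of enteroendocrine genes and proximal hormones with a covariate, were chosen after the result was seen, and both covariates were added after the data were seen. Within each group of 5 arrays, a value was picked out when the highest or lowest array lay far from the rest, by Dixon's ratio of its gap to the whole range at a 95% level. This picked out 23 of 316 groups, where chance alone picks out about 1 in 20.

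The ileal genes were high in 4 of the 5 knockout arrays and low in knockout 1, whose list mean of -1.10 lay far from the 0.72 to 1.10 of the others. A swap of knockout 1 for a control is argued against, since its Pcyt1a lay 1.36 below the lowest control (a difference of -1.36 on the log2 scale, control SD 0.203). That tissue was taken further along the intestine in the knockouts cannot be told apart from an effect of the knockout. On a second pair of lists of position genes, the difference between groups of the proximal minus the distal mean was -0.494 (SE 0.308), under 2 SE from 0. The proximal list alone differed by -0.266 (SE 0.121) and the distal list by 0.229 (SE 0.216). On that distal list knockout 1 was at -0.51, the other knockouts at -0.02 to 0.55 and the controls at -0.42 to 0.20. A rise in every knockout array was not seen, since 4 of 5 lay above the highest control and knockout 1, whose Pcyt1a was low, had the lowest list mean of all 10 arrays, although 1 array alone does not rule out an effect of the knockout.

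The rise of ATF4 target genes was weighed against tissue position and against crypt share. With the ileum list mean as a covariate, the difference of the list mean was 0.503 (SE 0.146), against 0.482 (SE 0.108) without it. This argues against position as the whole cause, as far as the ileum list mean tracks position. With the crypt lists mean as a covariate the difference was 0.405 (SE 0.0466), which argues against crypt share as the whole cause, as far as that mean tracks it. That mean averages in the Paneth and stem cell lists, which differed little between groups. In both the ATF4 and the proliferation list, knockout 4 and control 3 were highest and knockout 5 and control 5 lowest in their groups. A larger share of dividing tissue therefore stays open as a part of the cause. An effect of the knockout is a hypothesis, found and tested on the same arrays.

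The lower enteroendocrine genes were weighed against tissue position. With the ileum list mean as a covariate the difference of the list mean was -0.307 (SE 0.102), against -0.267 (SE 0.0774) without it. This argues against position as the whole cause of the list's change, as far as the ileum list mean tracks position. For the proximal hormones Gip, Cck and Ghrl the difference of the mean was -0.270 (SE 0.0905) with the covariate, against -0.638 (SE 0.179) without it. Knockout 1, at 0.27, lay among the controls (0.09 to 0.48) while the other knockouts were at -0.67 to -0.25. The ileum list mean may track position only in part, so position stays open for these hormones, as a part or the whole of the cause. The hormones made more distally, Nts, Pyy and Gcg, which like Cck and Ghrl are outside the naming rule and would be higher in tissue taken further along, had a mean difference of -0.306 (SE 0.403), which decides nothing. Control 5 lay far from the other controls in the enteroendocrine list mean, at -0.14 against 0.16 to 0.24.

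Among list means, knockout 1 stood apart for phospholipid remodelling (-0.20 against 0.22 to 0.25), knockout 3 for epithelial defence (-0.17 against 0.19 to 0.32), knockout 4 for the circadian clock (-0.35 against -0.11 to -0.06) and knockout 5 for the NRF2 list (-0.22 against 0.07 to 0.11). Among controls, control 3 stood apart for PC and PE synthesis (6.81e-04 against 0.08 to 0.11), control 4 for smooth muscle (0.95 against -0.33 to -0.06) and control 5 for macrophages (-0.76 against 0.03 to 0.34).

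Among genes, given as log2 intensity, the knockout arrays that stood apart were knockout 3 for Reg3g (12.25 against 12.94 to 13.11) and Reg3b (12.95 against 13.51 to 13.69), knockout 1 for Dgat2 (12.33 against 10.66 to 11.03) and Nsdhl (8.81 against 9.20 to 9.32), and knockout 5 for Plk1 (7.29 against 8.36 to 8.52). Control 5 stood apart for Srebf1 (10.01 against 8.84 to 9.02), Siglecf (6.998 against 6.69 to 6.77) and Itgam (6.18 against 6.78 to 6.94), and control 3 for Aurka (7.28 against 6.50 to 6.68) and Birc5 (6.42 against 5.37 to 5.65). Control 4 did so for Gclm (10.71 against 10.18 to 10.26), control 2 for Ms4a1 (6.40 against 3.82 to 4.44), and control 1 for Lyve1 (8.23 against 7.74 to 7.87) and Slc4a1 (6.04 against 5.52 to 5.62).

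Outside the tested genes, in a test of all probe sets, 13 passed the threshold, of which 12 were unnamed and 1 carried several gene symbols.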

How the results depend on the processing

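The fits with the ileum or the crypt covariate and the fit without knockout 1 and control 5 together were chosen after the data were seen. Pcyt1a passed under all 20 alternatives, at -1.78 to -1.63. All 76 called genes kept their direction wherever they were tested. The groups did not overlap in these genes, so leaving out or weighting arrays could not turn it. Over all alternatives, 1987 results for named genes kept direction and side of the threshold, 270 were weaker, 77 stronger and 1 reversed, and for lists these counts were 734, 49, 15 and 34. The number of arrays limits precision, and signal over background was not measured here.

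The 76 genes (38 higher, 38 lower) became 142 (70, 72) with array weights, 261 (117, 144) at a threshold of 0.1, and 39 (23, 16) with all probe sets tested. They became 5 (3, 2) with the ileum covariate, where the median SE of the 76 was 1.24 times as large and the median ratio of their changes 0.887, 196 (111, 85) with the crypt covariate, and 186 (80, 106) without knockout 1 and control 5. With 1 array left out they ranged from 11 to 268 (higher 6 to 113, lower 5 to 155). With the replicate number as a block they were 27 (15, 12). Of the 76, 16 kept their call in that fit. Same-number correlations ran from -0.135 to 0.125, and 0 arrays correlated best with their own number. These values gave no sign that the numbers pair the samples, but they do not exclude it. Lists called were 0 of 38 with an estimated correlation and 7 with fry, against 17.

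Reversed list means, none of them called in the first fit except PPARA targets, were as follows. Tight junctions were at -2.52e-04 with quantile normalization, -0.0159 with array weights and -0.0922 with the ileum covariate. With array weights ER stress was at 8.56e-04, macrophages at -0.0601 and endothelium at -0.0204. With the ileum covariate PPARA targets were at 0.00641, B and plasma cells at -0.0725 and the gene Ms4a1 at -0.11. Macrophages were at -0.0471 with the crypt covariate. Without knockout 1 and control 5, stem cells were at -0.12, macrophages at -0.23 and endothelium at -0.0248. With 1 array left out, the ranges were -0.0640 to 0.0139 for ER stress, -0.50 to 0.13 for Paneth cells, -0.12 to 0.14 for stem cells, -0.28 to 0.12 for MHC class II, -0.0315 to 0.0350 for tight junctions, -0.0480 to 0.0166 for apoptosis, -0.17 to 0.10 for macrophages, -0.17 to 0.15 for smooth muscle and -0.0214 to 0.0865 for endothelium. The cause of these shifts was not tested.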

Other observations

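The lists of aminoacyl-tRNA synthetases and peroxisomal genes were chosen after the called genes were seen, and the tests of their means were set before the values of their members were looked at, while the test of the synthetases with a crypt covariate was chosen after the result was seen. Aminoacyl-tRNA synthetases, which load amino acids onto tRNA and many of which are known ATF4 targets, had higher values in knockout in 18 of 18 measured genes. The values include 0.53 (SE 0.12) for Gars and 0.49 (SE 0.18) for Mars1, picked after they were seen, and 0 genes passed over all genes. The hypothesis that the rise of ATF4 targets extends to these genes stays open. Their mean difference was 0.318 (SE 0.160), just under the 2 SE set for the test, and the groups overlapped, with knockout 5 at -0.25, control 3 at 0.186, knockout 3 at 0.185 and knockout 1 at 0.0999. With the mean of the crypt lists as a covariate the difference was 0.208 (SE 0.0787). That covariate averages in the Paneth and stem cell lists, which differed little between groups. By array, the synthetase means had the same signs as the proliferation list means, above 0 in knockouts 1 to 4 and control 3 and below 0 elsewhere. A larger share of crypt or dividing tissue therefore stays open as the cause.

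Hsd17b4 (-0.44, SE 0.08), Pipox (-0.94, SE 0.17) and Dao, 3 called genes of peroxisomal enzymes of which Hsd17b4 and Pipox are outside the naming rule and were picked after the calls were seen, led to the hypothesis that other peroxisomal genes fell with them. The mean difference of 27 others was -0.0817 (SE 0.0588), between 1 and 2 SE from 0, so the question stays open. Of these, 11 had higher and 16 lower values and 0 passed, with Acot4 at -0.57 (SE 0.12) and Cat, catalase, at -0.52 (SE 0.12), both picked after their values were seen.

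The 10 arrays can be divided into 5 and 5 in 126 ways, and 100 of these, the real one among them, were tested in the same way. For genes, 2 of 100 gave at least 76 calls, the real one and 1 with 679, which argues against chance division as the source of that count. For lists, 7 of 100, the real one included, gave at least the real 17, and the others had a median of 10 and a highest of 19, so the number of lists called could come from chance division. Fry called 7 lists in the real division, and the highest of the others was 6.

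The division with 679 genes put knockouts 1 to 4 and control 3 on 1 side and knockout 5 with controls 1, 2, 4 and 5 on the other. It shared 4 genes with the 76. Noticed afterwards, this is the order of the proliferation list means, which were 0.23 to 0.68 on the first side and -0.78 to -0.06 on the second.

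Neighbouring called genes were counted as a test of a passenger region or transgene insertion. There were 2 pairs within 5 tested genes in gene order, Rdh16f2 with Hsd17b6 and Ubxn8 with Gsr, where Hsd17b6 and Ubxn8 are outside the naming rule. Random gene sets of the same size gave a median of 1, and 36.3% of 10000 sets gave as many. Called genes were thus not clustered beyond random sets. A single small region would add few pairs, so this count cannot exclude that source. Ubxn8 and Gsr, adjacent in gene order, were both higher, while Rdh16f2 was lower and Hsd17b6 higher.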
